A study of Mus musculus with 64 samples.

How the data were processed

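RNA from T cell populations of MC38-bearing mice was sequenced in bulk. Per the labels, each library was sequenced in a pair of runs that were then merged by the authors. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the mouse genome build GRCm38. Their versions, settings and roles are not given in the sources used here.

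Samples were assigned to groups from their titles, which give the tissue, the arm, the cell type and a replicate number, before the data were examined. A plan of 24 gene-level comparisons and 26 gene lists was fixed at the same point.

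The header of the deposited count table was then compared with the labels. Each column name, whole and without its final sequencer index, was searched for in the labels of every sample, ignoring case and punctuation. Sample identifiers and the lists of deposited data were left out of this search. None of the 64 names was found. The labels used here do not state the order of the library codes, so columns were not assigned by order. They were not assigned by the expression of marker genes either, since that would have assumed differences the comparisons were meant to test. No per-sample value of the 64 columns entered a result, and the planned comparisons, their alternatives and the gene lists were not run. Replicate spread and pairing by replicate number need that assignment and were not analysed here. Column totals need no assignment, but they are not reported as depth, because no column was tied to a sample of the series.

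Gene identifiers and coordinates in the table were compared with the GENCODE M21 annotation. A gene's extent was taken as the lowest exon start and the highest exon end in the table, and was compared with the gene record of the annotation on chromosome, start and end.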

Results

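The series concerned RNA from T cells of mice bearing MC38, a mouse colon carcinoma cell line. Foxp3 is the transcription factor that defines regulatory T cells (Treg), and the mice carried a Foxp3-Cre-YFP reporter. The labels described 64 bulk RNA libraries, made with a SMART-seq chemistry, which amplifies full-length cDNA from small amounts of RNA. Per the protocol, the mice were given 250000 MC38 cells. Isotype antibody or antibody against PD-1, an inhibitory receptor of activated T cells, was given on days 7, 10 and 13.

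The libraries fell into 16 groups of 4. These groups crossed 2 tissues (tumour and non-draining lymph node), 2 cell types (Treg and CD4+ Foxp3-negative T cells) and 4 arms. There were 32 libraries from each tissue and 32 of each cell type. The isotype arm held 16 libraries. The other 48 were labelled anti-PD1 and were divided by their titles into 3 arms called NR, EARLY and LATE. The labels used here did not expand these names, and they are kept as written. The antibody days were the same for all libraries, isotype included, so they do not tell the arms apart. Because NR, EARLY and LATE share the anti-PD1 label, they are not taken to be separate treatments.

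The design implied a comparison of tumour with lymph node within each cell type, a comparison of Treg with Foxp3-negative CD4 T cells within each tissue, and comparisons of the anti-PD1 arms with isotype and with one another. None of these comparisons was made. The count table held 64 columns of values, headed by library codes, 32 beginning with BDHY and 32 with Lib_BD. The names of 0 of the 64 columns occurred in any of the labels searched for the 64 samples. No column was therefore assigned to a tissue, cell type or arm, and no expression value, fold change or test is reported for any gene.

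The gene rows were compared with a reference annotation without using the values. The table listed 46517 genes by Ensembl identifier, with exon coordinates. Of these, 46005 were found in the GENCODE M21 annotation of the mouse genome build GRCm38, and 512 were not. The outermost start and end of the exons, with the chromosome, were identical in both sources for 38860 of the 46005 genes and differed for 7145. The annotation release behind the table was not given in the sources used here, so these differences were not read as errors.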

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

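No paired analysis was possible because the columns of the count table carry no names that were found in the labels searched. No column was therefore tied to a sample or to its replicate number. No result was computed from expression values, so none of the alternatives planned for the gene comparisons was run. Alternatives for the name and annotation checks were chosen after seeing the table. A wider search used only the letters that precede the number in a column name, which are BDHY or Lib_BD. Neither string occurred in the labels searched, so this also found 0 of 64. With the annotation of the reference chromosomes alone, the same counts were obtained, 46005 genes found and 38860 with identical coordinates, so that setting removed none of the table's genes and says nothing about stability.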
